A study of Mus musculus with 3 samples.

How the data were processed

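CD8+ T cells of MC38 tumours from 20 mice were sorted into 4 populations, marked by hashtag antibodies 1 (PD1−), 4 (D1), 5 (D2) and 6 (D3) per the labels' protocols, and pooled into 1 capture that gave 3 libraries, of gene expression, receptor sequences and antibody tags. The authors processed them with Cell Ranger 9.0.1, per the submitters' processing notes and the file headers, against the mouse genome build GRCm39, per the submitters' processing notes; the run configuration names an older build, GRCm38, for the receptor reference. The deposited values were raw UMI counts per gene or antibody and cell barcode, and UMI counts per assembled receptor contig. The deposited matrix held 3563 barcodes, 33696 genes and 28 antibodies, of which 19 were surface proteins, 5 isotype controls and 4 hashtags. Gene symbols were used as the deposited feature list gives them, and no coordinates were used.

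Barcodes were assigned to populations with HTODemux of Seurat 5.3.0 in R 4.3.3 (centred log ratio over cells, positive quantile 0.99). This gave 2988 singlets, 572 barcodes with more than 1 hashtag and 3 with none; only singlets were used. The median own-hashtag count was 3156.5, 4990, 4621.5 and 4718.5 UMIs in PD1−, D1, D2 and D3, and that of the highest other hashtag 79, 81, 83 and 62. Among the barcodes with more than 1 hashtag, 198 (5.56% of all) had no hashtag at 4 times the second one. Doublets of different populations were thereby removed, and doublets within a population were not removed; their number was estimated at 66.6 (2.23%) from these 198, and would be 192.3 if all 572 were doublets, though 374 of them had a top hashtag at 4 times the second. No other doublet caller was run. Cells needed at least 500 genes and at most 10% mitochondrial UMIs. A barcode without a UMI of Cd3d, Cd3e, Cd3g, Cd8a or Cd8b1 and with 2 or more markers of 1 other cell type was left out. These filters kept 2916 cells.

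UMIs were summed over the cells of each population and divided by the population's total to give CPM. Ratios between populations have exact conditional (Clopper-Pearson) 95% intervals, and shares have exact binomial ones; all cover counting error only, neither animals nor sorting. Log2 ratios were taken after adding 0.5 UMI to each population. With 1 sample per population, no p-value was computed. A gene with 0 UMIs in a population was compared with a floor of 3 UMIs over that population. The genes named in the text follow a rule: for each comparison the 12 genes with the highest and the 12 with the lowest log2 ratio among those past the rule of size, without receptor segments and numbered predicted genes; for each list up to 3 members with the most extreme ratio and up to 3 with the highest CPM; and a short fixed set of exhaustion and aldehyde genes. Some genes that this rule picks are not reported here. The rule of size, the gene lists, the naming rule and the alternatives listed below were chosen before the data were examined, except where stated.

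In all, 38 gene lists were used, on T cell states, metabolism, stress, repair, cell cycle and other cell types. A list's median was taken over members with at least 10 CPM in a population, and was ranked by its percentile among 10000 random lists matched on mean expression in 20 bins. The percentile, given for part of the lists, describes these libraries and is no test. Cycling cells were those with UMIs of 3 or more of 10 cell cycle genes. Receptor clonotypes were defined by TRB V gene and CDR3 nucleotide sequence among cells with exactly 1 productive TRB contig, with size counted over the 4 populations, and the Morisita-Horn index of each pair was set beside the mean index of 100 random splits of each population into a pair of equal parts. Antibody UMIs per cell were compared without scaling, since the cells had been stained in 1 mix per the labels' protocols, and next to the isotype controls.

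The gene comparison was tested on simulated data with 50 genes at each of the folds 1.5, 2, 3 and 4 for every comparison. At a fold of 2 the rule counted 62% of the changed genes for D1 with PD1− (2893 genes run), 58% for D2 with D1 (2906), 52% for D3 with D1 (2978) and 50% for D3 with D2 (2969). At folds of 3 and 4 it counted 100% in each of the 4, at 1.5 it counted 0%, and 0 unchanged genes were counted. The UMIs were drawn with counting noise only, which is what the intervals assume. The simulation therefore checks the calculation and says nothing about variation between cells, clones, sorts or animals. In simulated hashtag counts of 3038 cells, HTODemux assigned 97.6% of singlets to the right population and found 100% of doublets. The simulation held a smaller share of doublets than HTODemux called in the data. It therefore does not show how many of the 572 called barcodes were doublets. MULTIseqDemux called 3438 singlets in the data, against 2988.

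The alternatives were another hashtag caller (MULTIseqDemux) and a ratio rule for the top hashtag (at least 4 times the second), other cell filters, edgeR 4.0.16 TMM factors, totals without receptor, ribosomal and mitochondrial genes, equal weight for each cell, thinning to 1500 UMIs, other thresholds, leaving out cycling cells, the most frequent clonotype or cells with 2 TRB contigs, and equal weight for shared clonotypes. The clonotype setting kept only cells of clonotypes with 3 or more cells in both populations compared. Where cells or clonotypes are weighted alike, intervals come from the summed UMIs of the same cells. For receptors they were the Cell Ranger clonotype, a size of 5 cells and equal cell numbers (1000 draws), and for antibodies other scalings. Removal of barcodes by the Cd3 genes alone, the restriction to cells with a TRB contig and clonotype size within a population were added after the data were seen. Other computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.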

Results

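CD8+ T cells from MC38 tumours were profiled by single-cell RNA sequencing together with surface antibody tags and T cell receptor sequences. MC38 is a mouse colon carcinoma line. Tumours of 20 untreated wild-type mice were pooled on day 14, and 4 populations of viable CD45.2+ CD8a+ cells were sorted: a PD-1-negative population (PD1−) and the subsets D1, D2 and D3 of the PD-1-positive cells. PD-1 is an inhibitory receptor found on activated and exhausted T cells. The labels do not give the gates that set D1, D2 and D3 apart; the cells had been stained with the mitochondrial dyes MitoTracker Deep Red and MitoTracker Green before the sort. The study's title concerns aldehydes, metabolism and CD8+ T cell exhaustion, and the populations allow 4 comparisons, D1 with PD1−, D2 with D1, D3 with D1 and D3 with D2.

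After assignment by hashtag antibody and cell filters, 630 PD1−, 792 D1, 752 D2 and 742 D3 cells were analysed. Their gene UMIs summed to 5052805, 7090602, 10389468 and 13507514. The median cell held 7069.5 UMIs in PD1−, 8634.5 in D1, 12395.5 in D2 and 16079 in D3, and the median number of genes detected was 2199, 2644.5, 3265.5 and 3800.5. Mitochondrial UMIs made up 1.17%, 0.880%, 0.941% and 0.991% of the median cell. Each population was 1 sample from 1 pool and 1 capture, so no difference has a replicate check and no test between populations was made. Intervals are exact 95% intervals that cover counting error only. A gene was counted as different when it had at least 50 CPM (its UMIs scaled to the population's total) in the higher population, a ratio of at least 2, and an interval bound of at least 1.5 on the side nearer to no difference.

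D1 was compared with PD1− to ask what sets this PD-1-positive subset apart from PD-1-negative cells of the same tumours. Genes of exhaustion, glycolysis and low oxygen and several genes of killing were higher in D1, and genes of naive and memory T cells were higher in PD1−. Nrgn, which encodes a calmodulin-binding protein, stood at 167 CPM in D1 and 4.16 in PD1−, a 40.2-fold difference (26.2 to 65.2). Gzmf, a granzyme gene, was 66.4-fold higher in D1 (45.5 to 101), and Tnfrsf4, which encodes the costimulatory receptor OX40, 16.9-fold (12.6 to 23.1). Tcf7, a transcription factor of naive and stem-like T cells, was 12.8-fold higher in PD1− (10.6 to 15.6). Pdcd1 itself was 16.3-fold higher in D1 (14.1 to 18.9); it encodes PD-1, on which the cells were sorted, so it checks the labels.

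By the rule of size, 156 genes were higher in D1 and 159 were higher in PD1−. Of the 24 measured genes of the terminal exhaustion list, 21 lay above a ratio of 1 and 12 passed the rule, with a median log2 ratio of 1.27 (percentile 100 among random lists of matched expression). The inhibitory receptor genes Lag3 and Havcr2 were 7.53-fold (6.78 to 8.38) and 4.48-fold (3.72 to 5.43) higher in D1. Tox, a transcription factor of exhausted cells, was 3.32-fold higher (2.89 to 3.82), and Entpd1, which encodes the ectonucleotidase CD39, 2.36-fold (1.95 to 2.86). In the cytotoxicity list, 9 of 28 genes passed the rule upward and 2 downward, with a median of 0.51. Prf1, which encodes perforin, was 6.09-fold higher in D1 (5.24 to 7.11), whereas Gzmb differed by 1.15-fold and the granzyme gene Gzma and the chemokine gene Ccl5 were 10.5-fold (9.43 to 11.8) and 2.74-fold (2.68 to 2.79) higher in PD1−. Klrh1, a killer cell lectin-like receptor gene, had 115 CPM in D1 against 1 UMI in PD1−, a ratio of 579 (104 to 22883).

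The glycolysis list had a median log2 ratio of 0.93 (percentile 100), with 9 of 22 genes past the rule. Slc16a3, a lactate transporter gene, was 5.21-fold higher in D1 (3.88 to 7.13), and the glycolytic enzyme genes Aldoa and Gapdh were 2.16-fold (2.08 to 2.24) and 2.11-fold (2.06 to 2.17) higher. In the hypoxia list, 23 of 24 genes lay above a ratio of 1 and 8 passed the rule, with a median of 1.04. Bnip3, a mitophagy receptor gene induced by hypoxia, was 4.88-fold higher (3.85 to 6.26), and Hilpda, a lipid droplet gene induced by hypoxia, 9.37-fold (8.12 to 10.9). The naive and central memory list lay lower in D1, with a median of −1.65 (percentile 0) and 8 of 20 genes past the rule. The progenitor exhaustion list had a median of −0.84, with 8 of 22 genes past the rule downward and 1 upward. These 2 lists share Tcf7, S1pr1, Klf2 and others. S1pr1, needed for exit from tissue, was 16.4-fold higher in PD1− (11.5 to 24.1), and Klf2, which drives it, 4.68-fold (4.48 to 4.90). Medians near 0 were found for TCR signalling (−0.03) and for dissociation and heat stress (−0.04). In the TCR signalling list 4 of 27 genes passed the rule upward and 3 downward, so its median covers opposite differences. Tissue residency (0.28), p53 targets (0.37), apoptosis (0.32), S phase (0.26) and G2/M phase (0.25) lay above 0. Interferon response (−0.37) and cytosolic ribosomal proteins (−0.19) lay below 0.

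Genes of other cell types were also higher in PD1−. The plasmacytoid dendritic cell gene Siglech had 202 CPM in PD1− and 0 UMIs in D1, at least 477-fold lower against a floor of 3 UMIs in D1, and Tyrobp, an adaptor of myeloid and NK cells, was 309-fold higher in PD1− (168 to 646). The dendritic cell list had a median of −4.94 over 11 genes, the macrophage list −4.54 over 3, the NK cell list −3.97 over 6 and the B cell list −2.15 over 3. The list of CD4 and regulatory T cell genes had a median of 0.91 over 6 genes, led by Tnfrsf4 and by Ctla4 at 4.00-fold (3.68 to 4.35), while Cd4 itself was 8.49-fold higher in PD1− (5.32 to 14.2). The MC38 and epithelial list had a median of −0.24 over 3 genes. Fewer than 3 listed genes reached 10 CPM in a population for fibroblasts and endothelium (2), neutrophils (0), gamma-delta T cells (0) and erythrocytes (0). In PD1−, 27 barcodes (4.29%, 2.84 to 6.17) had no UMI of Cd3d, Cd3e or Cd3g and 3 or more dendritic cell markers; with barcodes of that kind left out, 122 genes were higher in PD1−, 107 of them among the 159, and S1pr1 and Tcf7 were 17.7-fold (12.4 to 26.1) and 13.9-fold (11.5 to 16.8) higher. Lag3 was then 11.8-fold higher in D1 (10.3 to 13.5). Genes of other cell types were still among the 122, with Siglech at 50.9 CPM in PD1− and Tyrobp 76.3-fold higher (41.1 to 160).

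**Figure D1:**
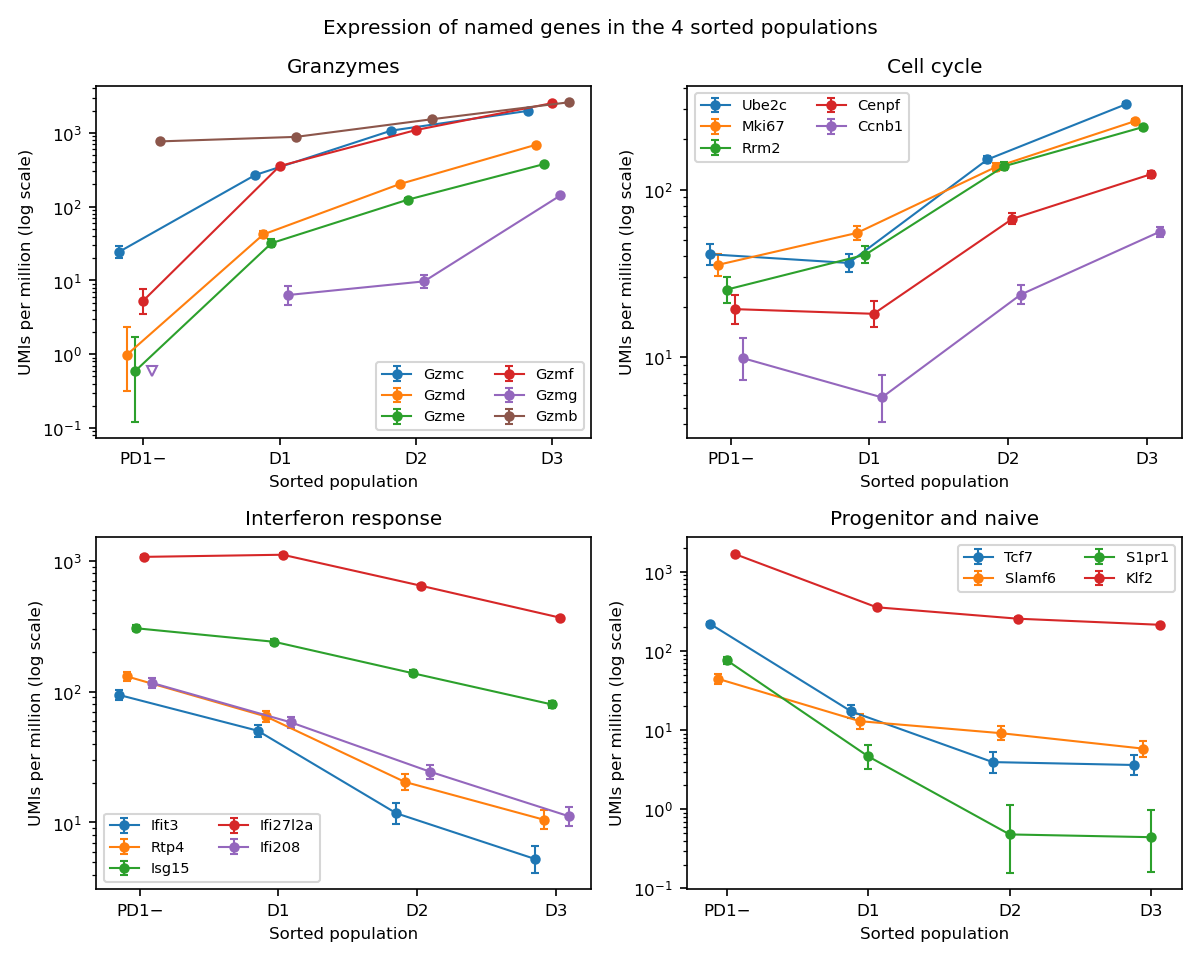
CPM (log scale) of granzyme, cell cycle, interferon response and progenitor or naive genes in the 4 sorted populations; each point is the summed UMIs of 1 population, bars are exact 95% intervals for counting error, and open triangles mark 0 UMIs, drawn at the floor of 3 UMIs. Gzmc went from 24.3 in PD1− to 1982 in D3, and Ifit3 stood at 50.2 in D1 and 5.26 in D3.

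D2 was compared with D1 within the PD-1-positive cells. Genes of cell division and the granzyme genes Gzmc, Gzmd and Gzme were higher in D2, and interferon response genes were lower. Gzmd stood at 202 CPM in D2 and was 4.80-fold higher than in D1 (4.25 to 5.44), and Gzme was 3.88-fold higher (3.37 to 4.49). Ube2c, a ubiquitin-conjugating enzyme of mitosis, was 4.13-fold higher (3.62 to 4.73), and Rrm2, a subunit of ribonucleotide reductase, 3.36-fold (2.96 to 3.83). Ifit3, an interferon-induced gene, was 4.28-fold higher in D1 (3.47 to 5.30), and Rtp4, another, 3.16-fold (2.68 to 3.74).

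By the rule of size, 51 genes were higher and 7 lower in D2. In the G2/M phase list, 50 of 50 genes lay above a ratio of 1 and 15 passed the rule, with a median log2 ratio of 1.38. In the S phase list, 42 of 42 lay above and 3 passed, with a median of 0.75. The proliferation marker Mki67 was 2.47-fold higher in D2 (2.21 to 2.77), and Prf1 2.10-fold (1.99 to 2.22). The interferon response list had a median of −0.79 (percentile 0), with 37 of 37 genes below a ratio of 1 and 4 past the rule. The progenitor list (−0.47), the naive list (−0.38), TCR signalling (−0.31), dissociation and heat stress (−0.26) and tissue residency (−0.26) lay below 0. Tcf7 was 4.36-fold higher in D1 than in D2, from 17.2 to 3.95 CPM (3.04 to 6.37), below the level the rule asks for. The terminal exhaustion list did not stand apart (−0.05, percentile 19.1), nor did cytotoxicity (0.00, percentile 43.4); 5 genes of the latter passed upward and Ccl5 downward, 2.29-fold (2.23 to 2.35). Cytosolic ribosomal proteins (−0.02) and apoptosis (−0.12) lay near 0, and p53 targets stood at 0.09. Among other cell types the medians were 1.12 for macrophages, 0.16 for dendritic cells, −0.28 for B cells, −0.01 for NK cells, 0.02 for CD4 and regulatory T cells and −0.18 for MC38. Cells with 3 or more of 10 cell cycle genes made up 11.4% of D1 and 31.1% of D2, and without them 10 genes were higher in D2, all among the 51. Of 103 clonotypes shared by D1 and D2, 21 had 3 or more cells in both. With these 21 weighted alike and all other cells left out, several directions turned. On the log2 scale the interferon list stood at 0.089, Ifit3 at 0.14, Rtp4 at 0.58 and tissue residency at 0.092. Under this setting 0 of the 7 lower genes, Ccl5 (−0.88) included, passed the rule.

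D3 was compared with D1, again within the PD-1-positive cells. The granzyme genes Gzmc to Gzmg and genes of cell division were higher in D3, interferon response genes were lower, and most genes of the exhaustion list differed little. Gzmg stood at 142 CPM in D3 and 6.35 in D1, a 22.3-fold difference (16.6 to 30.7), and Gzmd was 16.4-fold higher (14.6 to 18.4). Gzmb was 2.94-fold higher (2.86 to 3.02) and Prf1 3.39-fold (3.22 to 3.58). Ccnb1, which encodes cyclin B1, was 9.68-fold higher (7.07 to 13.6). Ifit3 was 9.55-fold higher in D1 (7.39 to 12.5), and Isg15, a ubiquitin-like protein gene induced by interferon, 3.01-fold (2.79 to 3.25).

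By the rule of size, 143 genes were higher and 46 lower in D3. The G2/M list had a median of 2.25, with 29 of 50 genes past the rule, and the S phase list 1.17, with 15 of 42. Mki67 was 4.62-fold higher (4.16 to 5.15). The interferon list had a median of −1.44, with 37 of 37 genes below a ratio of 1 and 11 past the rule. The metallothionein genes Mt1 and Mt2, which bind metal ions, were 4.45-fold (4.17 to 4.75) and 4.55-fold (3.89 to 5.35) higher in D3. In the terminal exhaustion list the median was −0.16 (percentile 4.13). Havcr2 was 1.61-fold higher in D3 (1.49 to 1.75), Lag3 differed by 1.01-fold (0.975 to 1.05) and Entpd1 by 1.03-fold (0.919 to 1.15), and Tox was 1.57-fold higher in D1 (1.45 to 1.70). The cytotoxicity median was −0.04 (percentile 35.3), with 7 genes past the rule upward and Ccl5 downward, 3.63-fold (3.53 to 3.74).

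Several lists lay lower in D3 than in D1: progenitor exhaustion (−0.69), dissociation and heat stress (−0.62), TCR signalling (−0.57), tissue residency (−0.53) and naive and central memory (−0.52). Some of them share genes, as Cd69 and Xcl1 are in the progenitor, TCR signalling and tissue residency lists. Their medians are therefore not independent results in any comparison. Fos, an immediate early gene, was 2.30-fold higher in D1 (2.19 to 2.41), and Bst2, induced by interferon, 2.02-fold (1.87 to 2.18). Tcf7 was 4.74-fold higher in D1 (3.38 to 6.75) and Slamf6, a surface receptor of progenitor exhausted cells, 2.22-fold (1.62 to 3.04), both under 50 CPM in D1; without cycling cells the D3 to D1 ratio of Slamf6 was 0.739 (0.495 to 1.09). Apoptosis (−0.10) and cytosolic ribosomal proteins (−0.10) lay near 0. The medians of other cell types were 0.29 for macrophages, −0.22 for dendritic cells, −0.58 for B cells, 0.38 for NK cells, −0.10 for CD4 and regulatory T cells and 0.06 for MC38. Cycling cells made up 51.9% of D3, and the share with 3 or more cell cycle genes was 2.86% in D1 (1.80 to 4.30), 13.1% in D2 (10.8 to 15.8) and 30.7% in D3 (27.4 to 34.3) once each cell was thinned to 1500 UMIs. That step left out 23, 14 and 23 shallower cells. Without cycling cells 47 genes were higher in D3, 25 of them among the 143, and 25 were lower, 22 among the 46. With only the 18 clonotypes of 3 or more cells in both D1 and D3, weighted alike, the interferon median was −0.50. Under this setting 26 genes were lower, 11 among the 46. Ifit3 then no longer passed the rule, with a log2 ratio of −0.70 and, in the summed UMIs of these clonotypes, a D3 to D1 ratio of 0.636 (0.315 to 1.32), at 19.8 CPM in D1; Isg15 stood at −0.79 on the log2 scale. Ccl5 no longer passed either, at −0.70 and a summed ratio of 0.549 (0.504 to 0.599), and the intervals of the summed ratios of Tcf7 (0.0808 to 2.33) and Slamf6 (0.238 to 2.42) included 1.

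D3 was compared with D2 to see what differed between these subsets. Granzyme genes were again higher in D3, with the cell cycle genes by smaller ratios. Gzmg was 14.6-fold higher in D3 (11.9 to 18.0), Gzma 3.65-fold (3.35 to 3.99) and Gzmd 3.41-fold (3.25 to 3.58). The chemokine gene Ccl1 stood at 225 CPM in D3 and 70.4 in D2, 3.20-fold higher (2.95 to 3.48), and Serpinb9b, a serpin gene, was 2.52-fold higher (2.19 to 2.90). By the rule of size, 17 genes were higher in D3 and 1 was lower, the receptor segment Trav12-2, which the naming rule leaves out and which was named after its value was seen.

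The G2/M median was 0.81, with 6 of 50 genes past the rule, and the S phase median 0.35. Without cycling cells, which were picked by cell cycle genes, these medians were −0.11 and −0.21. Interferon response (−0.53) had 36 of 37 genes below a ratio of 1 and none past the rule. Terminal exhaustion (−0.11), progenitor (−0.21), naive (−0.18), TCR signalling (−0.23), tissue residency (−0.25) and dissociation stress (−0.23) lay below 0, as did cytotoxicity (−0.03), ribosomal proteins (−0.07) and apoptosis (−0.02). The medians of other cell types were −0.37 for macrophages, −0.38 for dendritic cells, −0.30 for B cells, 0.38 for NK cells, 0.05 for CD4 and regulatory T cells and 0.30 for MC38. The number of higher genes was 28 with each cell thinned to 1500 UMIs, 12 of them among the 17. Without cycling cells it was 14, 6 of them among the 17. With only the 33 clonotypes of 3 or more cells in both D2 and D3, weighted alike, it was 39. Of these 39, 11 were among the 17, and Gzma then had a log2 ratio of −0.99. Gzmc to Gzmg lie in 1 family of similar sequence, so UMIs can be split between them with error. Their sum was 31.3 CPM in PD1−, 703 in D1, 2499 in D2 and 5714 in D3, 8.13-fold higher in D3 than in D1 (7.90 to 8.36) and 2.29-fold higher in D3 than in D2 (2.25 to 2.32).

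Lists of energy metabolism and of aldehyde removal were compared because the study's title names aldehydes and metabolism. No gene that clears aldehydes passed the rule of size, which asks for at least 50 CPM in the higher population. Listed genes below that level could not pass at any ratio, as Aldh2 and Cbr1 (13.9 and 22.8 CPM in PD1−) for D1 with PD1−. For such genes the rule cannot decide. Akr1a1, Park7 and Esd, at 219.7, 155.8 and 144.6 CPM in D1, were above the level. Of 41 listed genes, 19 reached 10 CPM in a population, and the median log2 ratio was 0.00 for D1 with PD1− (percentile 25.4), 0.09 for D2 with D1 (91.8), 0.16 for D3 with D1 (93.0) and 0.05 for D3 with D2 (67.7). In D3 against D1, 8 of the 19 genes had an interval above 1. Aldh7a1, an aldehyde dehydrogenase gene, was 1.92-fold higher in D2 than in D1 (1.37 to 2.73), at 12.99 CPM in D2, below the level that the rule asks for. Adh5, which oxidises formaldehyde bound to glutathione, stood at 69.5 CPM in D1 and 76.8 in D3, a ratio of 1.11 (0.992 to 1.23). Glo1, which clears methylglyoxal, had a ratio of 1.03 (0.896 to 1.18), and that of Gpx4, which reduces lipid peroxides, had an interval of 1.04 to 1.17. Aldh2, the mitochondrial aldehyde dehydrogenase, had 13.9 CPM in PD1− and 4 UMIs in D1, a 24.6-fold difference (9.18 to 92.6). Without the barcodes that had no Cd3 UMI and markers of another cell type, Aldh2 stood at 2.78 CPM in PD1− and the difference was 4.93-fold (1.52 to 20.8).

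Most nuclear genes of oxidative phosphorylation were higher by small amounts in D3 than in D1. Their median over 77 genes was 0.18 for D1 with PD1−, 0.14 for D2 with D1, 0.23 for D3 with D1 and 0.07 for D3 with D2, and 70 of 77 lay above a ratio of 1 in D3 against D1, against 62 of 77 in D1 against PD1−, where the median of all genes was 0.085. Mitochondrially encoded genes stood at −0.38, 0.08, 0.21 and 0.11 in the same order. Mitochondrial ribosome genes had medians of 0.17, 0.15, 0.29 and 0.13, TCA cycle genes 0.13, 0.07, 0.20 and 0.09, and fatty acid oxidation 0.15, 0.10, 0.14 and 0.02. Among random lists, the percentiles for D1 with PD1− were 95.8 for oxidative phosphorylation, 96.6 for the mitochondrial ribosome, 65.6 for the TCA cycle and 77.3 for fatty acid oxidation, and for D3 with D1 they were 100, 100, 99.45 and 93.5. Glycolysis stood at 0.30, 0.46 and 0.09 and hypoxia at 0.18, 0.15 and 0.06 in the last 3 comparisons. Ldha, which makes lactate, was 1.60-fold higher in D3 than in D1 (1.56 to 1.64). Lipid and sterol synthesis had medians of −0.22, 0.19, 0.29 and 0.16; with the barcodes without Cd3 UMIs left out, the first was 0.038. Mitochondrial dynamics stood at 0.18, −0.04, −0.05 and −0.03, glutathione and antioxidant defence at 0.04, 0.09, 0.15 and 0.06, ferroptosis at 0.05, 0.08, 0.14 and 0.05, and the unfolded protein response at 0.02, 0.05, 0.19 and 0.13. Their percentiles were 86.1, 20.35, 33.9 and 13.5 for D1 with PD1− and 28.5, 98.2, 90.2 and 98.6 for D3 with D1. One-carbon metabolism had medians of 0.06, 0.29, 0.41 and 0.22, and Fanconi anaemia and crosslink repair 0.26, 0.27, 0.48 and 0.24. Without cycling cells the one-carbon median of D2 with D1 was −0.11, and the Fanconi medians of D2 with D1, D3 with D1 and D3 with D2 were −0.054, −0.063 and −0.14. The p53 target medians in D3 were 0.13 against D1 and 0.12 against D2.

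**Figure D2:**
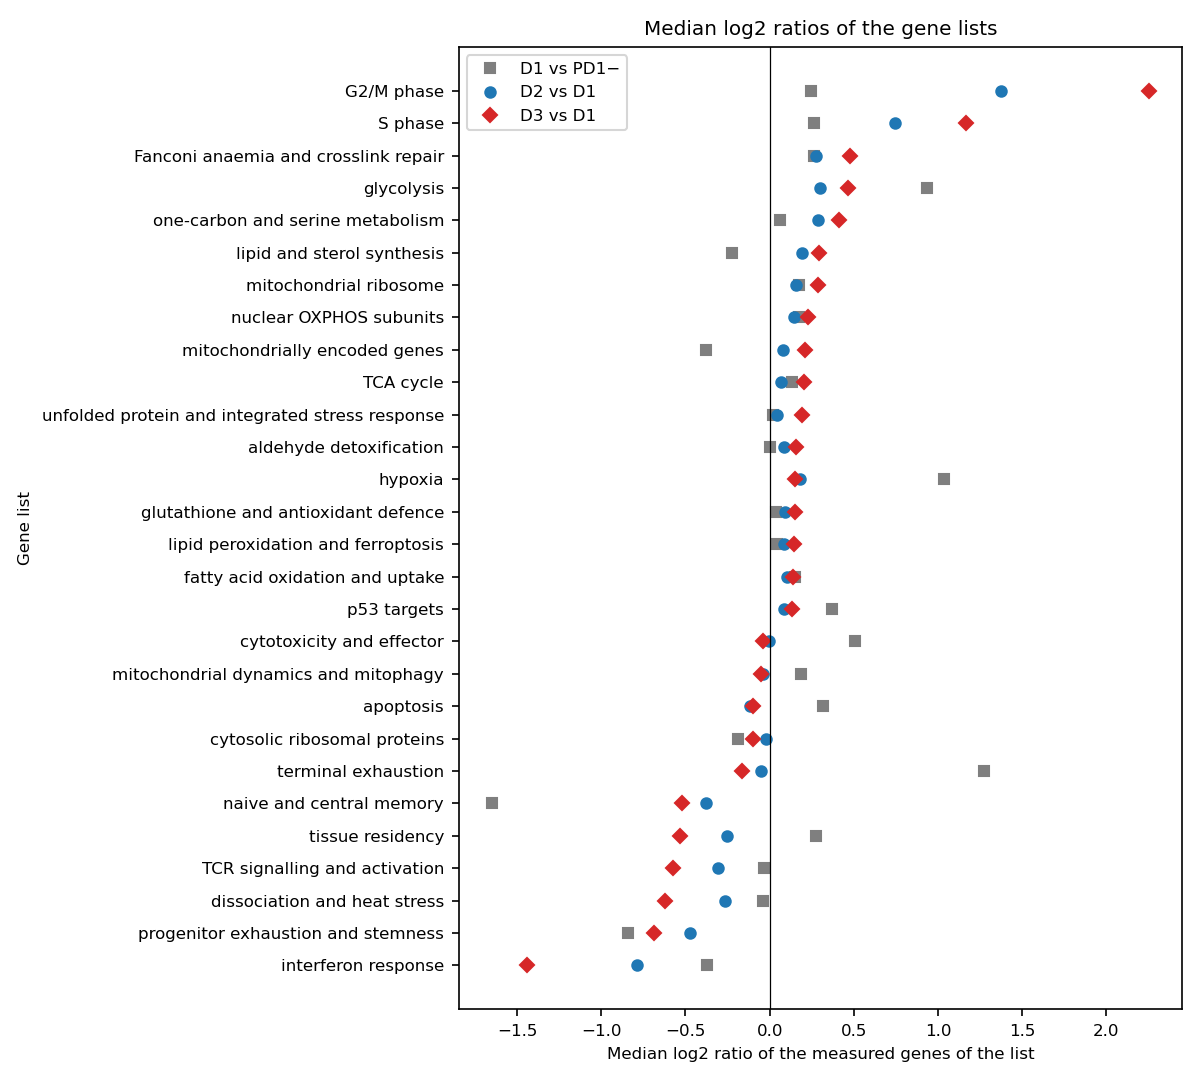
Median log2 ratio (horizontal axis) of the measured genes of each list for D1 against PD1− (grey squares), D2 against D1 (blue circles) and D3 against D1 (red diamonds), 1 value per list and comparison. Terminal exhaustion stood at 1.27 for D1 against PD1− and −0.16 for D3 against D1, while G2/M phase reached 2.25 for D3 against D1.

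Surface proteins were measured with 19 antibodies and 5 isotype controls in cells stained in 1 mix before the sort. TIM-3 (CD366), the protein of Havcr2, averaged 24.3 antibody UMIs per cell in PD1−, 149 in D1, 251 in D2 and 344 in D3, and was 2.30-fold higher in D3 than in D1 (2.29 to 2.32). CD39 averaged 43.2, 149, 206 and 295, a D3 to D1 ratio of 1.98 (1.96 to 1.99), and the adhesion receptor CD44 averaged 543, 1059, 1421 and 1687, a ratio of 1.59 (1.59 to 1.60). PD-1 averaged 2.70, 35.9, 46.3 and 53.9, which checks the sort, with an interval of 1.48 to 1.53 for the D3 to D1 ratio. In D1, D2 and D3, only CD366, CD39 and CD44 reached at least 3 times the highest isotype control of the same population. The isotype controls also differed, with D3 to D1 ratios between 1.64 and 2.02 and 1.68 for their sum. Of the surface antibodies, only CD183 and CD62L were not higher in D3 than in D1. As a share of all antibody UMIs, a total made up in large part of CD44, the ratios were 1.37 for CD366, 1.17 for CD39, 0.892 for PD-1 and 0.945 for CD44; an antibody with a smaller ratio than the total falls below 1 by construction. CD8a, which the naming rule lists, had no antibody in the panel.

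**Figure D3:**
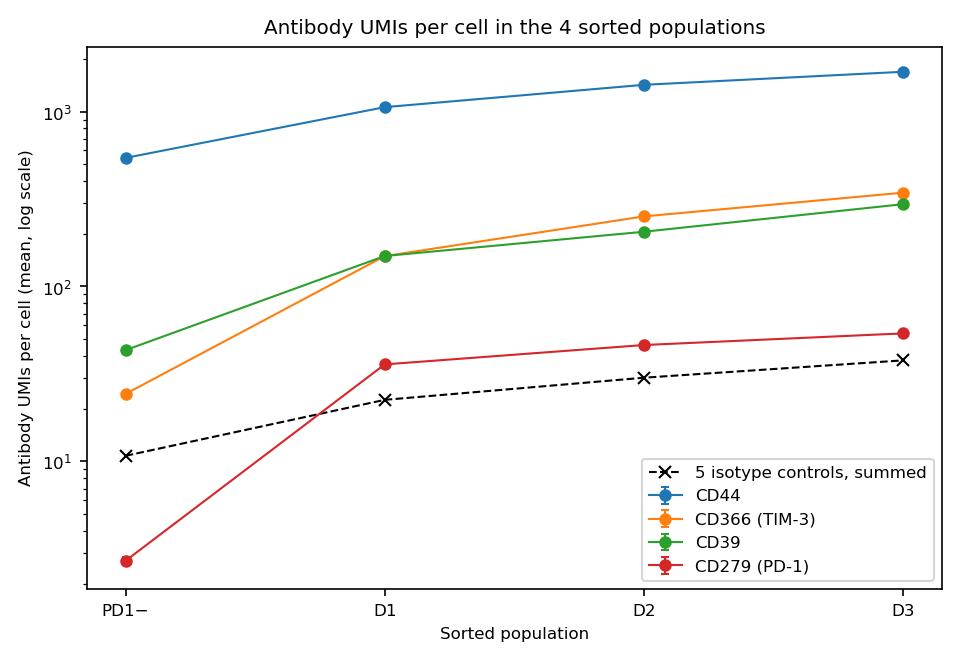
Mean antibody UMIs per cell (log scale) of CD44, CD366 (TIM-3), CD39 and CD279 (PD-1) and of the 5 isotype controls summed, in the 4 sorted populations; bars are exact 95% intervals for counting error and are smaller than the points. CD366 went from 149 in D1 to 344 in D3 and the summed isotypes from 22.5 to 37.8.

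T cell receptor sequences were compared to see how far the populations shared clones. PD1− was diverse, and the PD-1-positive subsets were expanded and shared clonotypes. Among cells with exactly 1 productive TRB contig (435, 520, 486 and 439), the share in clonotypes that held 2 or more cells over the 4 populations together was 23.7% in PD1− (19.8 to 28.0), 69.4% in D1 (65.3 to 73.4), 84.2% in D2 (80.6 to 87.3) and 88.4% in D3 (85.0 to 91.2). Clonotypes shared between populations raise these shares; with size counted within each population they were 16.6%, 55.8%, 68.7% and 72.9%. These cells formed 863 clonotypes, of which 244 held 2 or more cells and 76 held 5 or more. Of those 76, 49 had cells in D1, D2 and D3. The Morisita-Horn index, which is 0 with no shared clonotype and 1 for identical mixes, was 0.716 for D2 and D3, 0.566 for D1 and D2, 0.501 for D1 and D3, and 0.142, 0.0641 and 0.0628 for PD1− with D1, D2 and D3. With 50% of the cells drawn from each population it was 0.593 for D2 and D3, 0.448 for D1 and D2, 0.405 for D1 and D3, and 0.0985, 0.0474 and 0.0495 for PD1− with D1, D2 and D3. When each population was split at random into a pair of equal parts, the index between the parts was 0.149 in PD1−, 0.547 in D1, 0.624 in D2 and 0.689 in D3. The most frequent clonotype, TRBV20 with CDR3 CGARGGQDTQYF, had 14 cells in D1, 10 in D2 and 18 in D3 and none in PD1−.

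**Figure D4:**
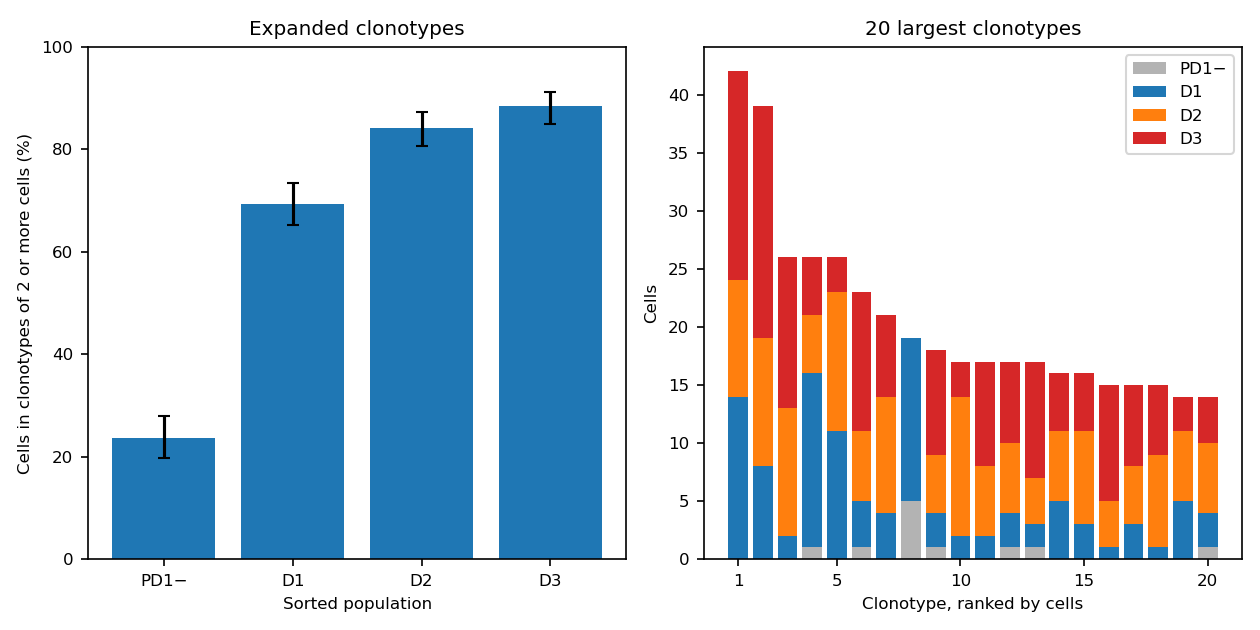
The left panel shows, for each population, the percentage of cells in clonotypes that held 2 or more cells over the 4 populations together, with exact 95% intervals for counting error; the right panel shows the number of cells of the 20 most frequent clonotypes, stacked by population. The share was 23.7% in PD1− and 88.4% in D3, and 19 of the 20 clonotypes had cells in D1, D2 and D3.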

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

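All of the values given here were looked at after the cell filters had been run, and no explanation was tested. The cell filters left out a larger part of D3 than of the other populations. They removed 42 of 784 D3 barcodes, 5.36% (3.89 to 7.17), against 2.33% of PD1− (1.31 to 3.81), 0.503% of D1 (0.137 to 1.28) and 1.44% of D2 (0.722 to 2.56). Of the D3 barcodes, 31 had fewer than 500 genes, 19 had over 10% mitochondrial UMIs and 2 had markers of another cell type, and a barcode can count under more than 1 filter. The median D3 cell that was kept held the highest number of UMIs of the 4 populations, 16079. Without the limits on genes and mitochondrial UMIs no count of genes differed by over 1.5 times from the one reported.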

How the results depend on the processing

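Removal of barcodes by the Cd3 genes alone, the restriction to cells with a TRB contig and clonotype size within a population were chosen after the data were seen; all other settings were fixed earlier. No paired analysis was possible because each population was 1 sample and the labels give no shared replicates. Of the values of gene list medians under alternatives, 966 stayed within the set margin, 22 differed without turning and 20 turned. For named genes these numbers were 1111, 261 and 8, and for the other results 131, 69 and 2. The settings with other CPM or ratio thresholds leave log2 ratios as they are. Their values for lists and named genes stayed by construction and say nothing on robustness. The 57 list medians were picked because they stood far out among random lists. A list's margin came from the spread of its own members. Clonotypes could not be weighted alike for D1 with PD1−, which shared 1 clonotype of 3 or more cells. The depth limits genes of low level: a count of 3 UMIs is 0.594 CPM in PD1− and 0.222 in D3. No scaling moved the median of all genes by over 0.1 on the log2 scale. Equal weight for cells took the share of higher among all counted genes from 87.9% to 74.4% in D2 against D1, thinning to 1500 UMIs took it to 67.3%, and leaving out cycling cells took it to 55.6%. In the other direction, TMM took it to 91.7% and equal weight for shared clonotypes to 98.0%. Except where the construction of a setting shows it, the cause was not tested.

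Thresholds move the counts by construction. With CPM of at least 10, of at least 200, or a ratio of at least 1.5, the higher genes were 346, 59 and 344 in D1 against PD1−, 167, 13 and 109 in D2 against D1, 372, 34 and 309 in D3 against D1, and 39, 6 and 94 in D3 against D2. The lower genes were 463, 33 and 284, then 42, 1 and 58, then 156, 9 and 214, then 10, 0 and 11. Totals without receptor, ribosomal and mitochondrial genes gave 243 lower genes in D1 against PD1−. With every cell weighted alike, D2 against D1 had 32 higher and 11 lower genes and D3 against D2 had 29 and 0. Thinning to 1500 UMIs gave 18 lower genes in D2 against D1, and 28 higher and 0 lower in D3 against D2. The ratio rule for hashtags gave 11 higher genes in D3 against D2, and MULTIseqDemux 0 lower. With only TRB cells, D2 against D1 had 32 higher genes and D3 against D2 had 33 higher and 0 lower.

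Leaving out cycling cells removes cells by their cell cycle genes, so those genes move by construction. It left 10 higher genes in D2 against D1, 47 higher and 25 lower in D3 against D1, and 0 lower in D3 against D2. In D2 against D1 the log2 ratio of Rrm2 became −0.10 and the medians of one-carbon metabolism and Fanconi repair −0.11 and −0.054. In D3 against D1, Ccnb1 became −1.49, Hmmr −0.70, Fanconi repair −0.063 and G2/M phase −0.034. In D3 against D2, Ccnb1 became −2.003 on the log2 scale, Fanconi repair −0.14, S phase −0.21, G2/M phase −0.11 and the dendritic cell list 0.39.

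With clonotypes weighted alike, D2 against D1 had 1 lower gene, D3 against D1 had 26, and D3 against D2 had 39 higher and 6 lower. This setting both leaves out the cells of other clonotypes and changes the weights, and these effects were not separated. The cause was not tested. In D2 against D1 the log2 ratios turned for Ifit3 (0.14), Rtp4 (0.58), Ifi208 (0.41), the interferon list (0.089), tissue residency (0.092) and the macrophage list (−1.43). In D3 against D2 they turned for Gzma (−0.99) and for the macrophage (0.22), dendritic (0.085) and NK (−0.24) lists. The macrophage list, with 3 measured genes, also turned in D2 against D1 with MULTIseqDemux (−0.15) and thinning (−0.47), and thinning gave 0.29 for it and 0.038 for dendritic cells in D3 against D2. Lipid and sterol synthesis in D1 against PD1− was 0.038 with T cells taken by Cd3 genes alone and 0.21 with TRB cells only.

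Expanded shares with clonotypes of 5 or more cells were 8.74%, 42.3%, 58.2% and 65.1% in PD1−, D1, D2 and D3, lower by construction. With size counted within each population they were 16.6%, 55.8%, 68.7% and 72.9%, lower by construction too. The Cell Ranger clonotype gave 19.3% in PD1− and Morisita-Horn indices of 0.460 for D1 and D3 and 0.108 for PD1− and D1. The D3 to D1 ratios as a share of antibody UMIs were 0.892 for PD-1, 1.37 for CD366, 1.17 for CD39 and 0.945 for CD44, where every ratio is divided by that of the total. As medians per cell they were 3.84, 2.30 and 1.68 for CD366, CD39 and CD44. Subtraction of the isotypes gave 1.48 for PD-1 and 2.32 for CD366. MULTIseqDemux gave 2.23, 1.88 and 1.58 for CD366, CD39 and CD44, and the ratio rule 2.24, 1.88 and 1.58. For all of these the cause was not tested.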

Other observations

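The tests of free RNA, of unspecific antibody binding, of a factor alike for every antibody, and of dendritic-like barcodes with or without Cd3 UMIs were chosen only after the result was seen, as were the receptor values that open this part. Different TRB nucleotide sequences that encode the same V gene and CDR3 protein were more frequent in the PD-1-positive subsets. Of 818 protein sequences, 31 were encoded by 2 or more clonotypes, 76 clonotypes in all with 407 cells. Cells with such a receptor made up 2.99% of PD1− (1.60 to 5.06), 22.1% of D1 (18.6 to 25.9), 29.2% of D2 (25.2 to 33.5) and 31.2% of D3 (26.9 to 35.8). A share of cells follows the size of clonotypes; with each clonotype counted once per population, the shares were 2.83% (1.42 to 5.00), 13.2% (9.69 to 17.4), 18.7% (13.9 to 24.3) and 20.7% (15.2 to 27.1). TRBV12-2 with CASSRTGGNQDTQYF was encoded by 4 clonotypes and held 72 cells, 1 in PD1−, 16 in D1, 23 in D2 and 32 in D3. TRBV31 with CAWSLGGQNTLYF was encoded by 6 clonotypes and held 31 cells. Some of these sequences rest on a partner clonotype of 1 cell. For TRBV20 with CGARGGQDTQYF, 42 of 43 cells lay in 1 of its 2 clonotypes, so 1 cell made all 43 count. In contrast, the 4 clonotypes of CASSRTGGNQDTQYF included 1 of 39 and 1 of 14 cells. Partners of 1 cell were not left out, and sequence error as their source was not tested. The 20 mice were pooled, so clonotypes of different mice cannot be separated by label. The clonotype TRBV3 with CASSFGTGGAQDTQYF had 5 cells in PD1−, 14 in D1 and 0 in D2 and D3. Among the 76 clonotypes of 5 or more cells, 26 had more cells in D1 than in D3 and 41 more in D3 than in D1.

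Dendritic cell genes were far higher in PD1− than in D1. The sort asked for CD8a on the surface. Of the 27 PD1− barcodes with no Cd3 UMI and 3 or more dendritic markers, 27 had Cd8a UMIs and 25 had Cd8b1 UMIs. A TRB contig was found in 454 of all 630 PD1− cells and in 0 of these 27 barcodes. They held 77.2% of the PD1− UMIs of 12 PD1− genes that were not used to pick them, between the bounds of 80% and 50% set for and against this source, so by that test it stays open. With Cd3 UMIs allowed and no TRB contig, 50 barcodes held 94.6%, with Tcf4, a plasmacytoid dendritic cell gene not used to pick them, at 653.6 CPM. Lack of a contig in a single barcode says little, as only 454 of the 630 PD1− cells had 1 or more. Of the genes used to pick, 5 of the 15 listed genes also reached 10 CPM in D1. Of the 50, 23 had Cd3 UMIs, with a median of 22, and Cd3e stood at 279.7 and Trac at 69.9 CPM in the 50, so T cells or doublets with them may be part of this set. Free RNA would be spread over barcodes with their UMIs, and is argued against because the share of the 12 genes' UMIs in the 27 barcodes was 10.3 times their share of all PD1− UMIs (7.49%). Plasmacytoid dendritic-like cells that passed the sort are a candidate source, as a hypothesis.

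Antibody UMIs per cell were higher in D3 than in D1 for all surface antibodies but CD183 and CD62L, and for the isotype controls. Over surface antibodies and isotypes together they came to 1536 per cell in D1 and 2591 in D3. The values below are mainly for CD366, CD39, CD44 and PD-1. Unspecific binding at the level of the isotypes is argued against as the whole cause, since the highest isotype was higher by 9.68 UMIs per cell and CD39 and CD44 by 146 and 628, and the lowest ratio of the 4 after subtraction of the highest isotype was 1.39, for PD-1. A factor alike for every antibody, such as cell size or staining, would give 1 common ratio. The intervals of PD-1 (1.48 to 1.53), CD44 (1.59 to 1.60), CD39 (1.96 to 1.99) and CD366 (2.29 to 2.32) did not overlap. The 4 ratios therefore differed beyond counting error. The intervals leave out the spread between cells, so they cannot decide whether such a factor is the whole cause. The CD366 ratio of 2.30 lay above the highest isotype ratio plus 1 SD (2.17). The isotype with that highest ratio, rat IgG2b, had an interval of 1.70 to 2.41, so this limit cannot decide. For CD366, and for PD-1, CD39 and CD44 with a median ratio of 1.59, such a factor as the whole or part of the cause stays open. The ratios of PD-1, CD39 and CD44 lay above the lowest isotype ratio less 1 SD (1.49). However, 7 of 19 surface antibodies lay wholly below it, among them Ly108 (1.12), CD49d (1.27) and CD183 (0.753). A lower level of these proteins cannot be told from the lack of such a factor. The RNA of Slamf6, Itga4 and Cxcr3, which encode these 3 named proteins, had D3 to D1 ratios of 0.451, 0.615 and 0.119. RNA does not give the protein level. More cycling cells in D3 would not explain the isotypes alone, since their summed ratio was 1.55 without cycling cells. Cell size was not measured, and a biological difference in PD-1, CD39 and CD44 stays open and untested.

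Gzmc to Gzmg were higher in D3 than in D1. Without cycling cells the median log2 ratio of the 5 genes was 4.94, against 3.56 in all cells, which argues against a larger share of cycling cells as the cause. With the 18 clonotypes of 3 or more cells in both populations weighted alike it was 3.57, with single genes from 2.89 (Gzme) to 5.07 (Gzmg). This argues against a different mix of these 18 clonotypes as the cause. Cells of all other clonotypes were left out, so a part played by those stays open. UMIs shared between these similar genes would move counts within the family, whose sum was 8.13-fold higher in D3 (7.90 to 8.36). A difference in state between D1 and D3 is one hypothesis that may account for the pattern, found and examined in the same cells, and the gates that separate D1 from D3 were not used here.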
